A study of Mus musculus with 10 samples.

How the data were processed

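Native chromatin immunoprecipitation followed by sequencing (N-ChIP-seq, in which chromatin is not crosslinked) was carried out on neural stem and progenitor cells from the forebrain of mouse embryos at embryonic day 13.5. The cultures, kept in medium with epidermal and fibroblast growth factors at 20 ng/ml each, received water (control) or 10 mM crotonate, a short-chain fatty acid that cells convert to crotonyl-CoA, for 24 h. The labels name 10 libraries: H3K4me3, H3K9cr (crotonylation), H3K27ac, H3K27me3 and input, each in control and in crotonate. The 8 immunoprecipitated libraries each have a peak list and were used, with 1 library per mark and treatment. For the 2 inputs no list was used here. Groups were taken from the labels. The antibody catalogue numbers were the same in both treatments of each mark, but per the labels the vendor differed between treatments for H3K4me3 and H3K27me3 and was given only in control for H3K9cr and H3K27ac. They were taken as the same antibody, which the files do not show.

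Bowtie2 2.4.1, MACS2 2.2.7.1 and the genome build GRCm38 are named in the submitters' processing notes. The peak-calling settings, duplicate handling and use of the inputs are not given in the sources used here. Each list held the calls of 1 library, in the layout of a MACS2 peak table per the file headers. The deposited pileup is a coverage signal, the height of stacked fragments at the summit. The deposited fold enrichment is the ratio of that pileup to the local background, per the file headers. The authors' -log10 p-value and -log10 q-value describe the summit of each peak, and every list ended near a q-value of 0.05. Positions were given by the authors from 1, both ends included. These peak values are the authors' own and were used here only to describe, rank or match peaks within a list. All peaks lay on chromosomes 1 to 19, X and Y, so 0 were left out.

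Read totals are not given in the sources used here. The lowest background implied by any peak of a list, the pileup plus 1 divided by the fold enrichment and minus 1, was taken as a stand-in for relative depth. It does not measure enrichment. Shares carry exact (Clopper-Pearson) 95% intervals over peaks or genes that cover counting error only. They treat peaks and genes as independent, which neighbouring ones are not, and 1 library shows no spread between cultures. Reads without molecular identifiers are not independent molecules either.

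A peak was shared when at least 1 bp of it overlapped a peak of the other treatment's list for the same mark. Control peaks without a partner are called lost and crotonate peaks without a partner gained. Both words refer to the lists, so a peak just under the calling limit in the other library counts as lost or gained. To compare peaks of like strength, unshared peaks at a kind of site were set against the number given by peaks elsewhere in the same decile of -log10 q of the same list, with a range for counting error.

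Gene positions came from a RefSeq table of GRCm38.p6. Peaks were assigned to 21887 protein-coding genes. The table used here has no strand and no transcript starts, so windows of 1 kb either side of both annotated ends of each gene took the place of the promoter windows that had been planned. Some windows therefore lie at the 3' end of a gene or at a neighbouring gene. A gene lost or gained a mark when a peak touched its windows in 1 treatment only, so that a shared peak with moved edges can also give such a change. A gene was called bivalent when H3K4me3 and H3K27me3 peaks touched the window of the same end. For H3K9cr, overlap with the other marks was compared with 100 random placements of the same widths on the same chromosomes.

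With 1 library per mark and treatment there was no replicate error, no test between treatments and no p-value. The position of a count among 10000 random gene lists of equal size describes these libraries only. For changes, random lists were drawn from genes with the same control state of that mark, and for coincidences of changes also with the same control state of H3K4me3 and H3K27me3. A second drawing, added after the data were seen, also matched losses on the control state and the decile of the lost mark's -log10 q, and gains on the control state and the decile of the control H3K27me3 peak's -log10 q, for lists and for coincidences. For lists it was repeated with changes that have an unshared peak only.

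The comparisons, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The 18 lists cover neural stem and progenitor genes, neuronal differentiation, astrocytes, the oligodendrocyte lineage, the Hox clusters, mesoderm, endoderm and germ-layer regulators, pluripotency and germ line, Wnt, Bmp, Tgfb, Fgf and Shh signalling, cell cycle arrest and growth control, cell cycle and DNA replication, acyl-CoA metabolism and acylation machinery, Polycomb and trithorax proteins, the integrated stress and inflammatory response, housekeeping genes, and 4 lists of other cell types: microglia and blood, endothelial and mural, meningeal and mesenchymal, choroid plexus and ependymal. In the list for cell cycle arrest and growth control, 19 of 21 members were measured, since H19 and Meg3 are not in the protein-coding set.

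Named genes followed a fixed rule. For each mark they are up to 6 gains and 6 losses with the highest -log10 q among unshared gene-end peaks, and up to 6 gains and 6 losses among members of the lists by the same ranking, leaving out predicted genes. Up to 8 genes were taken for the leading transition out of the bivalent state, and 10 genes were always reported: Sox2, Nes, Pax6, Neurog2, Gfap, Olig2, Actb, Gata4, Hoxa9 and Cdkn2a. Some genes that the rule names are not reported here. Ribosomal protein genes, Naca, Rnaset2a, Rnaset2b, Srp54c and Hbq1b have near-identical copies or processed pseudogenes, and their peaks are uncertain.

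The steps were tested on simulated lists made from each real list by removing and adding known peaks, and 100% of the removed and added peaks were recovered. Removed peaks were deleted outright and added ones lay over 1 kb from control peaks, so this checks only the overlap step. Peaks that fall just under the calling limit were not simulated. Of 200 genes made to lose their gene-end peak, 100% were recovered, with 38 to 54 further calls at genes that share those peaks. Of 2000 random lists of 40 genes drawn with no effect, 6.4% lay outside the middle 95%, a share that changes with the size of a list and the frequency of a change. Alternatives changed the overlap rule, the strength limit, the number of peaks, the window, the merging of neighbouring peaks, the definition of bivalency and the chromosomes used. Windows at the H3K4me3-marked end only, whole gene bodies, changes with an unshared peak only, the omission of ribosomal protein genes and the further matched random lists were chosen after seeing the data. The planned window at the 5' end only was not run. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.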

Results

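Peak lists for H3K4me3, a mark of promoters, H3K9cr and H3K27ac, acylations of active chromatin, and H3K27me3, the mark set by Polycomb complexes, were compared between forebrain neural stem and progenitor cells kept in water and those given 10 mM crotonate for 24 h. Each of the 8 lists came from 1 library, so no difference reported has a replicate check, and the vendor labels of the antibodies were not alike in both treatments. Read depth is unknown. Its stand-in, the lowest implied background pileup, was 2.91 in control and 2.87 in crotonate for H3K4me3, 3.74 and 3.20 for H3K9cr, 3.11 and 2.68 for H3K27ac, and 2.69 and 2.67 for H3K27me3. The crotonate value was thus 0.986, 0.857, 0.861 and 0.992 times the control value in that order of marks. The median summit pileup of the peaks in each list was 423 in control and 374 in crotonate for H3K4me3, 74 and 41 for H3K9cr, 23 and 17 for H3K27ac, and 16 and 15 for H3K27me3. The median fold enrichment was 102 and 91.6, 14.7 and 9.42, 5.59 and 4.62, and 4.34 and 4.03 in the same order.

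The first comparison asked how much of the genome each mark occupied. H3K27me3 had 26031 peaks in control and 34707 after crotonate, which covered 45.9 and 51.02 Mb. H3K27ac had more but narrower peaks after crotonate: 52922 peaks of median width 881 bp covered 66.7 Mb in control, and 59868 peaks of median width 625 bp covered 58.4 Mb after crotonate. H3K9cr peaks numbered 31905 and 32666 and covered 45.5 and 43.1 Mb. H3K4me3 peaks numbered 17322 and 18001 and covered 27.1 and 28.7 Mb. The number of peaks depends on how broad domains are split. With peaks within 3 kb merged, the excess after crotonate was 3103 in place of 8676 for H3K27me3, below the 5220 in place of 6946 for H3K27ac, and 468 in place of 761 for H3K9cr, while the difference in covered length was 10.4 in place of 5.15 Mb for H3K27me3 and -4.83 in place of -8.29 Mb for H3K27ac.

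Peaks found in 1 treatment only were counted for each mark. For H3K4me3, 486 of the control peaks (2.81%, 95% interval 2.56 to 3.06) were lost and 1239 of the crotonate peaks (6.88%, 6.52 to 7.26) gained. For H3K9cr the numbers were 4824 (15.1%, 14.7 to 15.5) and 4991 (15.3%, 14.9 to 15.7), for H3K27ac 13391 (25.3%, 24.9 to 25.7) and 18024 (30.1%, 29.7 to 30.5), and for H3K27me3 6875 (26.4%, 25.9 to 26.95) and 15704 (45.2%, 44.7 to 45.8). With peaks within 1 kb counted as shared, the lost share was 15.7% (15.2 to 16.1) for H3K27me3, below the 17.8% (17.5 to 18.1) for H3K27ac. When shared peaks had to overlap by 50% of both, losses numbered 1026, 7800, 23793 and 15335 in the order of marks above, and with the stronger 50% of 1 list set against the full other list 0, 8, 715 and 1185. The excess of gains depends on the length of the lists, since the crotonate list was the longer one for every mark. With equal numbers of peaks, fewer H3K4me3 and H3K27me3 peaks were gained, and losses of no mark could become fewer. The base pairs covered in both treatments made up 0.882, 0.766, 0.602 and 0.621 of those covered in either, in the same order of marks.

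**Figure D1:**
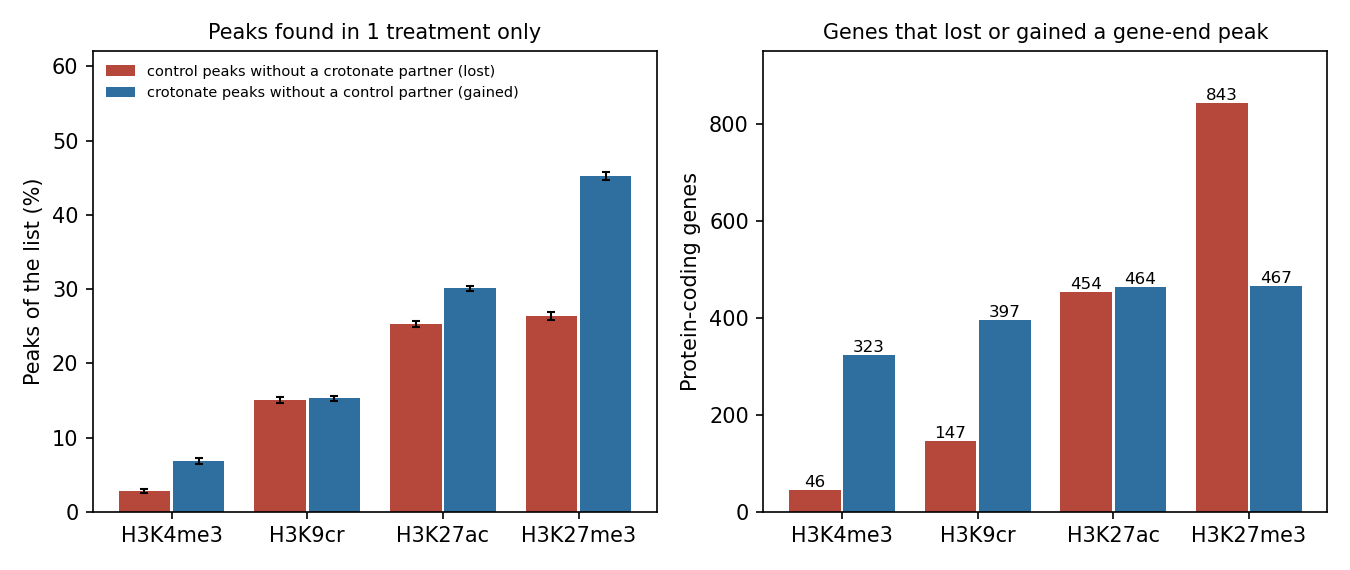
Left, percent of control peaks without a crotonate partner (lost) and of crotonate peaks without a control partner (gained) for each mark, with exact 95% intervals as bars. Right, number of protein-coding genes whose gene-end windows lost or gained each mark. H3K27me3 had the highest share of gained peaks, 45.2%, and yet more genes that lost it (843) than gained it (467).

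The unshared peaks of H3K27me3 lay at different places in the 2 treatments. Of the gained peaks, 10209 (65.0%) lay outside genes, against 48.0% of the shared crotonate peaks. Of the 5047 control H3K27me3 peaks that touched H3K4me3, 1103 (21.9%) were lost, 2.53 times the number expected from peaks elsewhere of like strength (range for no difference 0.920 to 1.08). Without regard to strength the order was the other one, since 16.0% (15.2 to 16.9) of all lost H3K27me3 peaks touched H3K4me3 and 20.6% (20.0 to 21.2) of the shared control ones. Gained H3K27me3 peaks touched crotonate H3K4me3 only 99 times, 0.135 times the expected number (0.95 to 1.05). H3K27ac gains lay in gene bodies in 70.2% of cases, 1.22 times the expected number (0.977 to 1.02), and H3K27ac losses in 56.8%, 0.941 times (0.977 to 1.02), whereas 43.2% of shared crotonate and 42.1% of shared control peaks did so.

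H3K4me3 and H3K9cr gains more often than losses lay at gene ends. Gene ends held 337 of the gained H3K4me3 peaks (27.2%) and 40 of the lost ones (8.23%), and 606 of the gained H3K9cr peaks (12.1%) and 224 of the lost ones (4.64%). Gained H3K4me3 peaks touched H3K27me3 in 45.3% of cases (42.5 to 48.1) and H3K27ac in 33.7% (31.1 to 36.4), whereas shared crotonate H3K4me3 peaks did so in 22.9% and 87.7%. Lost H3K4me3 peaks touched H3K27me3 in 13.4% and H3K27ac in 84.2%. Most unshared peaks were weak ones. The median lost peak stood at percentile 4.21, 13.0, 21.1 and 24.8 of its own list by -log10 q for H3K4me3, H3K9cr, H3K27ac and H3K27me3, the median gained peak at percentile 5.84, 12.9, 22.4 and 30.9.

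Chromosome X differed from the autosomes in H3K27me3 and H3K27ac. On X there were 693 H3K27me3 peaks in control and 498 after crotonate, whereas on the autosomes there were 25338 and 34209, with more after crotonate on 19 of 19 autosomes. Of the X peaks 55.6% (51.8 to 59.3) were lost and 30.5% (26.5 to 34.8) gained, against 25.6% (25.1 to 26.2) and 45.5% (44.9 to 46.0) on the autosomes. Gains of the acylations were also fewer on X: 11.1% (9.26 to 13.3) against 30.4% (30.1 to 30.8) of H3K27ac peaks, and 5.13% (3.70 to 6.89) against 15.5% (15.1 to 15.9) of H3K9cr peaks. Their lost shares had overlapping intervals. For H3K27ac they were 25.9% (23.4 to 28.5) on X against 25.3% (24.9 to 25.7), and for H3K9cr 16.3% (13.9 to 18.9) against 15.1% (14.7 to 15.5). H3K27ac peaks numbered 1128 and 996 on X but 51780 and 58865 on the autosomes, with more after crotonate on 19 of 19. H3K9cr peaks numbered 876 and 800 on X and 31019 and 31861 on the autosomes, with more on only 12 of 19. H3K4me3 peaks numbered 603 and 618 on X and 16714 and 17377 on the autosomes.

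**Figure D2:**
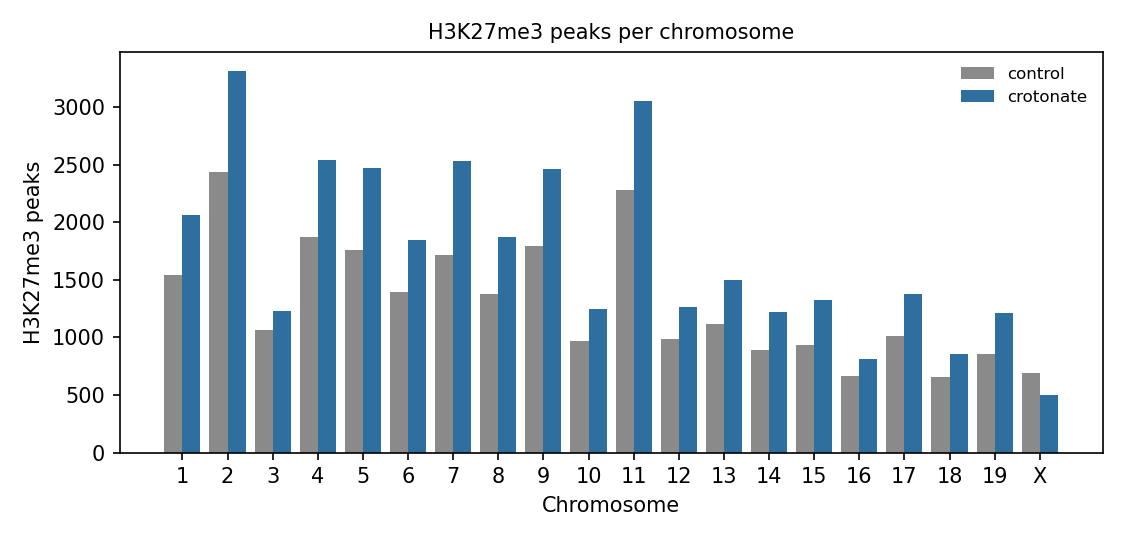
Number of H3K27me3 peaks on each chromosome in the control (grey) and crotonate (blue) lists, 1 library each; no H3K27me3 peak lay on Y. Every autosome has more peaks after crotonate, and X has fewer, 498 against 693.

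At gene ends, crotonate was accompanied by fewer genes with H3K27me3 and more with H3K4me3 and H3K9cr. H3K27me3 marked 4752 of the 21887 genes in control (21.7%, 21.2 to 22.3) and 4376 after crotonate (20.0%, 19.5 to 20.5), with 843 losses and 467 gains. With equal numbers of peaks fewer genes gained it, and the difference was -712. H3K4me3 marked 12920 (59.0%, 58.4 to 59.7) and 13197 genes (60.3%, 59.6 to 60.9), with 46 losses and 323 gains; with only the stronger 50% of each list, 154 genes lost it, and with an unshared peak asked for, 30. H3K9cr marked 13331 and 13581 genes, with 147 losses and 397 gains. H3K27ac marked 12550 and 12560 genes, with 454 losses and 464 gains. The difference of 10 genes for H3K27ac was -48 with windows of 500 bp, -146 with equal numbers of peaks and -78 at H3K4me3-marked ends, so it has no direction. At H3K4me3-marked ends losses and gains were 43 and 184 for H3K9cr and 280 and 202 for H3K27ac, and 85 genes gained H3K27me3. Under these and the other settings the difference for H3K27me3 lay between -712 and -104 genes.

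Genes with the strongest gained H3K4me3 peaks included Slc5a7, which encodes the choline transporter of cholinergic neurons, Npas1, a transcription factor of interneurons, Ltbp2, Tgm2, the transglutaminase 2 gene, and Il12b, a cytokine subunit. The Slc5a7 peak (chromosome 17, 54297890 to 54298831, at the upper annotated end of the gene, GRCm38) had a summit pileup of 107 and 27.9-fold enrichment in the crotonate list. Slc5a7 also gained H3K9cr, with 13.6-fold enrichment. Among list members, Lhx6, a regulator of cortical interneurons, Hoxa4, Hoxa13, Foxa2 and Hand1 gained H3K4me3. The strongest losses of H3K4me3 were at Spef1 and Ribc2, which encode proteins of cilia and flagella, Ankef1, Art3, Derl3 and Ltb4r1, with 8.43-fold to 11.8-fold enrichment in the control list. Mesp2, Pdgfrb and Ifit1 were the list members that lost it.

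H3K9cr was gained most strongly at Trh, the thyrotropin-releasing hormone gene, Slc5a7, Hbq1b, Slc6a21, Mogat1 and Cdh9, and among list members at genes including Col1a2, Anpep, Gjb6, Fgf17 and Ifit1. It was lost most strongly at Mb, the myoglobin gene, Ifi44l, N4bp2l1, Gjc3, Cibar2 and Lpin1, and among list members at Neurog1, Tbx4, Cldn5, Gpr17 and Sox18. Ifit1 thus lost a weak H3K4me3 peak and gained a H3K9cr peak. H3K27ac was gained most strongly at Cfap77 and Spag6l, which encode proteins of cilia and flagella, Gipc3, Ccdc152, Emc9 and Zfp750, and among list members at the inflammatory genes Icam1 and Cxcl1 and at Tbx3, Bmp3, Npy and Gdf7. Its strongest losses included those at Srp54c, Rnaset2a, Lrfn2, Rnaset2b and Mthfs, and among list members at Gpr17, Syp, Fgf18, Tubb3, Mesp2 and Lefty1. The copies of Hbq1b, Srp54c, Rnaset2a and Rnaset2b make their peaks uncertain.

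The strongest lost H3K27me3 peaks lay at Rpl9, Rpl36, Naca, Rpl6, Rps15 and Rpl35, and strong gained ones at Rpl7, Rps6 and Rpl27, genes of ribosomal proteins or, for Naca, of a chaperone at the ribosome. These were narrow peaks of 257 to 538 bp, and because such genes have many processed pseudogenes they are uncertain. Of 83 ribosomal protein genes, 34 had H3K27me3 in control and 26 after crotonate, with 11 losses and 3 gains. The other strong gains were at Gcm2, Nanog, the pluripotency factor, and Kif12. The Nanog peak (chromosome 6, 122707090 to 122708676) had a pileup of 22 and 6.27-fold enrichment. List members with strong losses were Rpl8, Rpl32, Id3, Bmp7, Ugt8a and Notch1, and those with gains were Mesp2, Cd3e and Ttr besides Rpl7, Rps6 and Nanog.

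The next comparison crossed H3K4me3 with H3K27me3, whose joint presence at a promoter is called bivalent and is common at developmental genes. Peaks of separate libraries from a whole culture do not show that both marks lay in the same cells. Bivalent therefore refers here to the peak lists only. Bivalent genes numbered 3492 in control and 3035 after crotonate, and genes with H3K4me3 alone 9288 and 10004. Of the genes bivalent in control, 741 (21.2%, 19.9 to 22.6) had H3K4me3 alone after crotonate, 10 had H3K27me3 alone, and 2718 stayed bivalent. Of the 1120 genes with H3K27me3 alone in control, 216 (19.3%, 17.0 to 21.7) were bivalent after crotonate and 72 had neither mark. Among the 741 were, by the rule, Rpl8, Rpl32, Id3, an inhibitor of differentiation, Bmp7, Ugt8a, Notch1, Fzd2 and Olig2.

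Loss of H3K27me3 among genes called bivalent went with H3K27ac. Of the 3492 such genes in control, 2561 (73.3%) also had H3K27ac at a gene end. The lists do not show whether these marks lay in the same cells. With H3K27ac at a gene end in control, 722 of 2561 bivalent genes lost H3K27me3 (28.2%, 26.5 to 30.0), and without it 22 of 931 (2.36%, 1.49 to 3.56). On autosomes only, the share without H3K27ac was lower. Genes with H3K27ac had weaker H3K27me3 peaks, so they were compared within quartiles of the control -log10 q. In the weakest quartile 67.3% (63.8 to 70.7) of bivalent genes with H3K27ac lost H3K27me3, 26.98% (16.6 to 39.7) of those without it, and 20.1% (15.9 to 24.8) of genes with H3K27me3 alone. In the strongest quartile the shares were 1.10%, 0 of 434 genes and 0 of 358 genes. With only the stronger 50% of each list, the share among bivalent genes without H3K27ac was 7.69%, the number of genes passing from bivalent to H3K4me3 alone 299 and from H3K27me3 alone to bivalent 123, and the difference in bivalent genes -175.

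**Figure D3:**
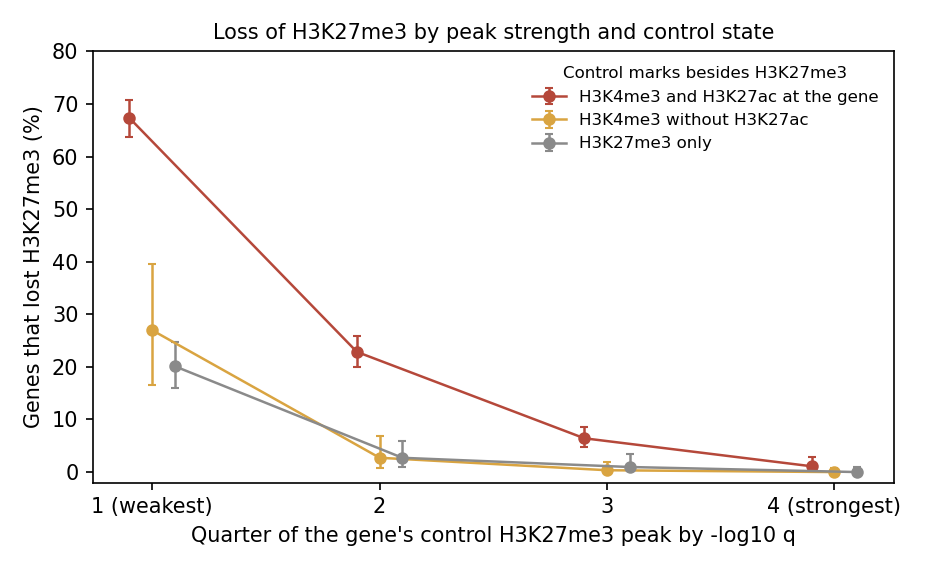
Percent of genes whose gene-end H3K27me3 was lost after crotonate, by quartile of the control H3K27me3 peak's -log10 q and by the other control marks; points are shares and bars exact 95% intervals. In the weakest quartile 67.3% of bivalent genes with H3K27ac lost the mark, against 26.98% without H3K27ac and 20.1% with H3K27me3 alone.

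Taken as whole lists, H3K9cr, a histone crotonylation for which crotonyl-CoA is the donor, lay mostly where other marks of active chromatin lay. In control 89.5% of H3K9cr peaks (89.2 to 89.8) touched H3K27ac and 52.6% (52.1 to 53.2) touched H3K4me3, against 5.32% and 2.08% for randomly placed peaks. After crotonate the shares were 81.0% (80.6 to 81.4) and 53.6% (53.1 to 54.2), against 5.20% and 2.11%. H3K9cr peaks touching H3K27me3 made up 19.4% and 16.0%, against 3.03% and 3.57%. Peaks of H3K9cr without any other mark numbered 965 in control (3.02%) and 2944 after crotonate (9.01%). Of the gained H3K9cr peaks, 42.7% (41.4 to 44.1) touched H3K27ac and 10.4% H3K4me3, against 87.9% and 61.4% of shared crotonate ones. Lost ones touched control H3K27ac in 89.0% of cases and H3K4me3 in 1.78%. Against peaks of like strength, gained ones touched H3K27ac 0.417 times the expected number (0.966 to 1.03) and H3K4me3 1.28 times (0.899 to 1.10). Lost ones touched control H3K27ac 2.25 times the expected number (0.918 to 1.08) and H3K4me3 0.176 times (0.920 to 1.08). Among bivalent genes 97.4% carried H3K9cr in control and 96.1% after crotonate, whereas among genes with H3K27me3 alone 14.7% and 12.9% did. H3K27ac marked 73.3% and 62.2% of bivalent genes, but these are 2 different sets of genes. Of the genes bivalent in control, 722 with H3K27ac and 22 without it lost H3K27me3. Another 216 became bivalent from H3K27me3 alone, a state in which 8.75% of genes carried H3K27ac in control. The lower share therefore does not show a fall of H3K27ac at the same genes. The median fold enrichment in these lists was 14.7 and 9.42 for H3K9cr and 5.59 and 4.62 for H3K27ac.

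Changes of H3K4me3 and H3K9cr fell on the same genes more often than in random lists. Of the 192 genes that gained H3K4me3 and had no H3K9cr in control, 116 gained H3K9cr (60.4%, 53.1 to 67.4), against a median of 27 in random lists (percentile 100). Of the 41 genes that lost H3K4me3 and had H3K9cr in control, 11 lost H3K9cr (median 0, percentile 100). Of all H3K4me3 peaks, 98.5% in control and 97.8% in crotonate touched H3K9cr. Random lists were not matched on this, so these counts do not separate a joint change from marks that lie together. Genes that lost H3K27me3 seldom lost H3K27ac: 20 of 754, against a median of 65 (percentile 0), and 16 of 89 without H3K27ac gained it, against 8 (percentile 99.8). These random lists were not matched on peak strength. Matched lists, added after the data were seen, left these 4 counts outside the middle 95%, with a median of 29 for the 20 H3K27ac losses (percentile 1.605). With equal numbers of peaks these 20 were 34. The same 16 genes were few among the 228 genes with H3K27me3 that gained H3K27ac, where random lists had a median of 41 losses of H3K27me3 (percentile 0) and matched lists 28 (percentile 0.055). Of 220 genes with H3K27me3 that gained H3K4me3, 3 lost H3K27me3, against a median of 15 (percentile 0) but of 5 in matched lists (percentile 15.6). Of the 24 different pairs of changes, each read from both sides, 4 lay above and 2 below the middle 95% of random lists from both sides, and 5 and 1 that of matched lists.

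Among neural stem and progenitor genes, 12 of the 25 with H3K27me3 in control lost it (48.0%, 27.8 to 68.7), including Ccnd1, Dll1, Egfr, Gli3, Hmga2, Id1, Id3, Notch1, Nr2e1 and Sox1. That list had 25 bivalent genes in control and 13 after crotonate, and 0 genes that gained H3K27me3. The count stood at percentile 99.985 of random lists but at 97.2 of lists also matched on state and peak strength, which had a median of 8 losses. With unshared peaks only, it was 11 genes, at 98.33 of matched lists. All 39 Hox genes kept H3K27me3, and 7 of 38 without H3K4me3 gained it: Hoxa4, Hoxa5, Hoxa6, Hoxa13, Hoxb7, Hoxb8 and Hoxd8 (11 with windows of 2 kb). The ends of the 39 genes lay under only 5 control H3K27me3 peaks on 4 chromosomes, so the genes are not independent observations, which percentiles among random genes ignore. Among mesoderm, endoderm and germ-layer regulators 0 of 56 lost H3K27me3, which allows a share of up to 6.38%. In that list 11 of 32 gained H3K4me3 (7 with equal numbers of peaks), including Foxa2, Gata2, Hand1, Hand2, Myod1 and Tbx20, 6 of 32 gained H3K9cr, and 3 of 9 (Mesp1, Mesp2 and Snai2) lost H3K27ac.

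Among the genes with H3K27me3 alone in control, 96 of 280 gained H3K4me3 in the quartile with the strongest H3K27me3 (34.3%, 28.7 to 40.2) and 17 of 280 in the weakest (6.07%, 3.58 to 9.54). Random lists matched on peak strength gave other positions. The Hox count of H3K4me3 gains moved from percentile 99.965 to 1.74, where matched lists had a median of 12 (4.47 with unshared peaks only), and their 2 H3K9cr gains (5 with windows of 2 kb) from 60.1 to 0.935. The germ-layer counts moved from 100 to 87.8 for H3K4me3 and from 99.865 to 46.7 for H3K9cr. The absence of H3K27me3 losses moved from 0.025 to 49.8 for the Hox genes and from 0 to 36.9 for germ-layer regulators. Of 142 pairs of list and change, 15 lay outside the middle 95% of random lists, but 6 outside that of matched lists, and 4 outside both, of which the Hox H3K4me3 gains lay above the first and below the second and 3 on the same side. Drawn lists of the same sizes with no effect gave 2.62 and 2.82 outside, fewer than 5%, because the changes were rare: a count of 0 lay inside the middle 95% for 137 and 126 of the pairs.

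**Figure D4:**
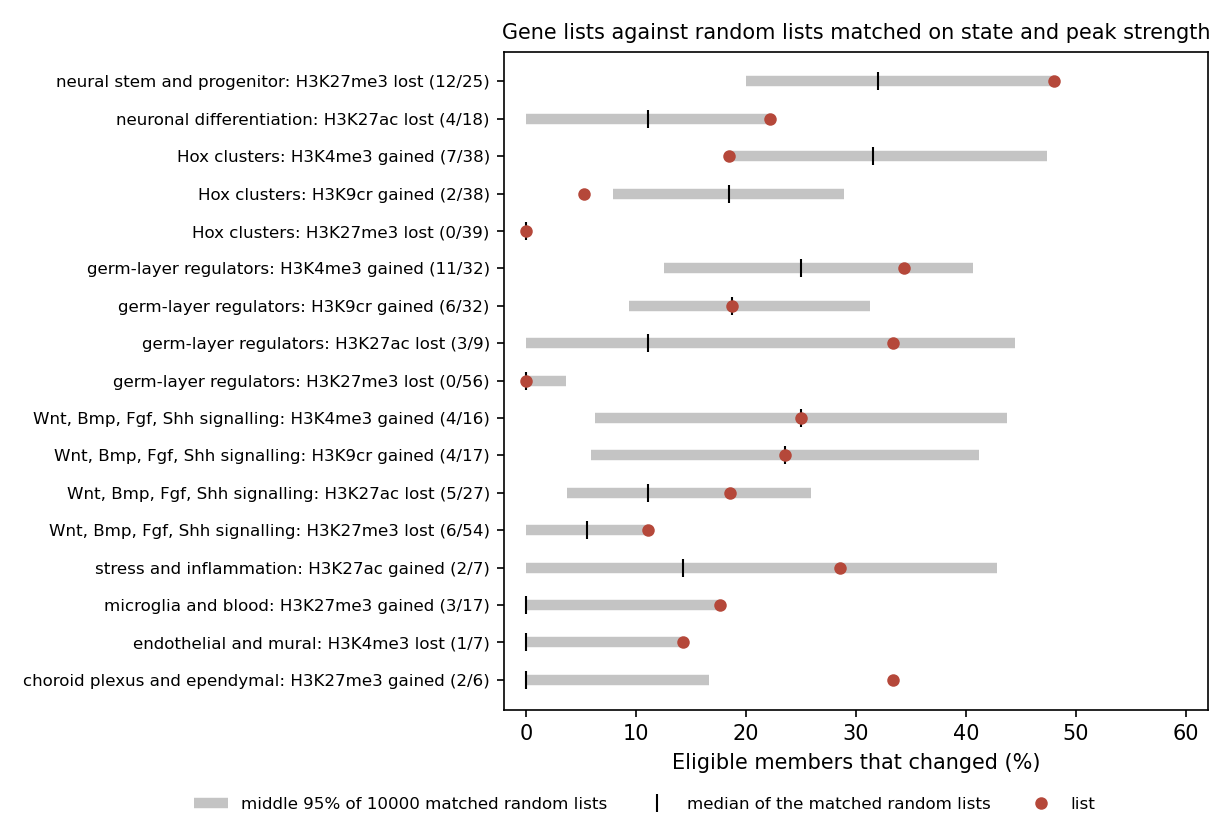
Percent of the eligible members of a list that lost or gained a mark (points, with counts in the row names), for the pairs of list and change outside the middle 95% of either kind of random list. Grey bars span the middle 95% of 10000 random lists matched on control state and peak strength and black ticks their medians; a point on the end of a bar can lie outside because of ties. The 2 H3K9cr gains among Hox genes lie below their bar, and the 12 H3K27me3 losses among neural stem and progenitor genes lie at its upper end.

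In Wnt, Bmp, Tgfb, Fgf and Shh signalling, 6 of 54 genes lost H3K27me3 (Bmp7, Fzd2, Fzd5, Sfrp2, Tcf7 and Wnt5a; percentile 9.91, matched 97.9), but 3 with windows of 2 kb. Only 2 of the 6 had an unshared peak, a count at percentile 0.985 of random and 66.97 of matched lists counted in that way. In the same list 4 of 16 gained H3K4me3 (Axin2, Ihh, Wnt9b and Wnt10b; 2 with equal numbers of peaks), 4 of 17 gained H3K9cr (Dkk1, Fgf17, Ihh and Wnt10b), and 5 of 27 lost H3K27ac (Bmp2, Fgf15, Fgf18, Gdf6 and Lefty1). All 3 of these counts lay outside the middle 95% of random lists and inside that of matched lists. Among neuronal differentiation genes 4 of 18 lost H3K27ac (Dlx1, Nefl, Syp and Tubb3; percentile 99.795, matched 96.2), and 5 of 46 lost H3K27me3 (Bcl11b, Dcx, Nefm, Neurod6 and Snap25). In the stress and inflammatory list 2 of 7 gained H3K27ac, Cxcl1 and Icam1 (percentile 97.525, matched 81.9), but 1 did with windows of 2 kb, and 2 of 9 lost H3K27me3.

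For the remaining lists no count of H3K27me3 loss stood outside the middle 95% of either kind of random list, except that with unshared peaks only the housekeeping losses stood at percentile 97.93 of random and 99.7 of matched lists. These housekeeping losses include Rpl8 and Rpl32, ribosomal protein genes whose peaks are uncertain. Losses numbered 2 of 6 among astrocyte genes (Cd44 and Sparcl1), 2 of 10 in the oligodendrocyte lineage (Olig2 and Ugt8a), 0 of 9 for pluripotency and germ line, 1 of 8 for cell cycle arrest and growth control (Gadd45g), and 0 of 2 for cell cycle and DNA replication. They numbered 3 of 8 in acyl-CoA metabolism and acylation machinery (Cdyl2, Hdac3 and Kat5), 2 of 10 among Polycomb and trithorax genes (Ezh1 and Jarid2), and 3 of 6 among housekeeping genes (Psmb2, Rpl8 and Rpl32). With windows of 2 kb they were 1 in the oligodendrocyte lineage, 0 for cell cycle arrest, 1 for cell cycle (as with equal numbers of peaks), 1 for acyl-CoA and 0 for Polycomb genes, and with unshared peaks only 0 for cell cycle arrest, 1 for acyl-CoA and 1 for Polycomb genes. Members named in this and the preceding paragraphs outside the rule were chosen after their values were seen.

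Among markers of other cell types 1 gene lost H3K4me3 and 0 gained it. H3K4me3 marked 5 of 24 microglia and blood genes in both treatments, 7 and 6 of 20 endothelial and mural genes, 10 of 14 meningeal and mesenchymal genes in both, and 8 of 13 choroid plexus and ependymal genes in both. H3K27me3 was gained at 3 of 17 microglia and blood genes (including C1qb and Cd3e) and at 2 of 6 choroid plexus and ependymal genes (Rsph1 and Ttr), and 1 of 7 endothelial and mural genes (Pdgfrb) lost H3K4me3. These 3 counts lay above the middle 95% of both kinds of random list, at matched percentiles of 98.5, 98.9 and 98.1, but with equal numbers of peaks 1 microglia and blood gene gained H3K27me3. The microglia and endothelial counts equalled the upper end of the matched range, 3 and 1, and lie outside because of ties. The lost Pdgfrb peak was weak, at percentile 1.31 of the control H3K4me3 list. Losses of H3K27me3 numbered 0 in each of the 4 lists, but 1 among endothelial genes with windows of 2 kb and 1 among choroid plexus genes with equal numbers of peaks. Of the members of these lists 0, 2, 4 and 1 stand also in another list, in the order given.

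Of the genes reported whatever their change, Sox2 and Nes, markers of neural stem cells, and Actb had H3K4me3 without H3K27me3 in both treatments. Olig2, a transcription factor of the oligodendrocyte lineage, lost a H3K27me3 peak (chromosome 16, 91225552 to 91226667, at the lower end of the gene) with 4.88-fold enrichment in the control list and had H3K4me3 alone after crotonate. Pax6, Neurog2 and the cell cycle inhibitor gene Cdkn2a were bivalent in both, and Pax6 lost a weak H3K27ac peak with 3.65-fold enrichment. Gata4 and Hoxa9 had H3K27me3 alone in both, within domains 48645 and 158612 bp wide in control. Gfap, the astrocyte marker, had H3K27me3 alone in both. A control H3K27ac peak with 5.84-fold enrichment touched its window and its crotonate partner did not, so this was not a lost peak.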

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

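The tests of H3K27me3 loss and of chromosome X, and that of H3K9cr at H3K4me3 gains, were chosen only after the result was seen; the other 2 tests of H3K4me3 gains were written before their results, though the shares touching H3K27me3 had been seen. Among the later tests, those of a raised background, of carry-over of active chromatin and of the number of X chromosomes were changed after a first run in which each had counted against its explanation, and that of H3K9cr at H3K4me3 gains was made stricter. The differences given here stand out because 2 marks or 2 kinds of chromosome moved in opposite directions in single libraries, and they were not tested.

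Crotonate minus control was -376 genes for H3K27me3 and 277 genes for H3K4me3, and among peaks of like strength H3K27me3 was lost more often where H3K4me3 lay, though 16.0% of all lost peaks touched H3K4me3 against 20.6% of shared ones. An evenly weaker crotonate library is argued against by 2.53 times as many lost peaks touching H3K4me3 as among peaks of like strength elsewhere (range 0.920 to 1.08). A raised background there stays open, since 27.7% (24.97 to 30.7) of crotonate H3K4me3 peaks at lost and 23.9% (22.6 to 25.2) at kept sites had a background above the library's lowest, against 25.9% and 27.7% in control, and how the inputs were used is not given in the sources used here. Carry-over of active chromatin into the control H3K27me3 library also stays open, since 3.19% (2.65 to 3.799) of genes with the strongest H3K27ac lost H3K27me3 against 10.1% (9.17 to 11.1) with the weakest, but 40.5% (34.9 to 46.4) against 20.6% (18.8 to 22.5) of those that had H3K27me3. Reads shared with pseudogenes could account for the 11 ribosomal protein genes that lost it, with no genome sequence used here to decide this. A response of bivalent genes to crotonate is among several open explanations. The lists do not separate such a response from a change in the mix of cells, which was not tested.

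For H3K27me3 peaks, crotonate minus control was -195 on X and 8871 on the autosomes and for H3K27ac -132 and 7085. For H3K27me3, a position of X peaks at the weak end of the control list is argued against by 1.86 times as many lost X peaks as among peaks of like strength on other chromosomes (range 0.893 to 1.11). Fewer X chromosomes in the crotonate culture, through another mix of male and female embryos, may contribute and cannot be told apart from a treatment effect: the ratio of X to autosomal pileup at shared H3K4me3 peaks was 0.589 (0.548 to 0.642) in crotonate and 0.554 (0.510 to 0.638) in control, while for H3K9cr it was 1.18 against 1.29 and for H3K27ac 1.08 against 1.15, with overlapping intervals. For H3K27me3 it was 0.842 (0.789 to 0.889) against 1.0 (0.895 to 1.06). More male embryos would also bring more Y chromosomes. Peaks on Y numbered 14 in control and 7 after crotonate for H3K27ac, 10 and 5 for H3K9cr, and 5 and 6 for H3K4me3. These counts are too small to decide on the mix of embryos.

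Gained H3K4me3 peaks touched H3K27me3 in 45.3% of cases (42.5 to 48.1), more often than the 22.9% of shared crotonate H3K4me3 peaks. As far as deciles match strength, evenly better enrichment is argued against by 1.56 times as many gained peaks touching H3K27me3 as among peaks of the same decile elsewhere (range 0.894 to 1.11). The median gained peak stood at percentile 5.84, and within the lowest decile a difference in strength can remain, so this explanation is not excluded. A fault of the H3K4me3 library alone was tested with the gains of H3K9cr, and the outcome met the criterion set against it. Of genes gaining H3K4me3 without H3K9cr in control, 60.4% (53.1 to 67.4) also gained H3K9cr, at percentile 100 of random lists with and without matching on H3K27me3 peak strength. The test cannot decide this, since 97.8% of all crotonate H3K4me3 peaks touched H3K9cr. Random lists were not matched on signal of these 2 marks under the calling limit. The genes were also not limited to those with H3K27me3, so a fault of that library stays open. Carry-over of H3K27me3 signal into the crotonate H3K4me3 library is consistent with the gain of H3K4me3 at 34.3% (28.7 to 40.2) of genes in the quartile with the strongest H3K27me3, against 21.4%, 16.8% and 6.07% (3.58 to 9.54) in the weaker quartiles. Larger CpG islands at such genes would give the same order and were not tested, so the pattern is not called biological.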

How the results depend on the processing

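The windows at H3K4me3-marked ends, whole gene bodies, the limit to unshared peaks, the omission of ribosomal protein genes and the matched random lists were chosen only after the result was seen. No paired analysis was possible because there was 1 library per mark and treatment and the results come from no test; leaving out a replicate was not possible for the same reason, and the window at the 5' end only was not run. Of 542 values under an alternative, 400 stayed within their limits, 110 moved, 23 left and 5 entered the outer 5% of random lists, and 4 changed direction. Of 360 values for named genes 296 stayed as reported and 64 did not, and by setting 90 of 90 stayed with equal numbers of peaks, 84 with windows of 2 kb, 79 with windows of 500 bp and 43 with the stronger 50% of each list. Crotonate minus control stayed above 0 for H3K4me3-marked genes (192 to 298) and H3K9cr-marked genes (141 to 367) and below 0 for H3K27me3-marked genes (-712 to -104) and bivalent genes (-669 to -175), and 655 to 1015 genes lost H3K27me3. H3K9cr and H3K4me3 were gained together at 93 to 135 genes. Depth limits these results through weak peaks, since a peak close to the calling limit in 1 library can be missing from the other list. Apart from the settings that by construction leave fewer peaks or ask for more overlap, the cause was not tested.

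With peaks within 3 kb merged, crotonate minus control was 468 H3K9cr peaks, 3103 H3K27me3 peaks, -4.83 Mb of H3K27ac and 10.4 Mb of H3K27me3. When peaks within 1 kb counted as shared, 4081 H3K27me3 peaks were lost. When shared peaks had to overlap by 50% of both, losses were 1026 for H3K4me3, 7800 for H3K9cr, 23793 for H3K27ac and 15335 for H3K27me3, and gains 8561 for H3K9cr, 30739 for H3K27ac and 24011 for H3K27me3. With the stronger 50% of 1 list set against the full other list, losses and gains were 0 and 0 for H3K4me3, 8 and 19 for H3K9cr, 715 and 1342 for H3K27ac, and 1185 and 3604 for H3K27me3.

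With the stronger 50% of each list, lost and gained peaks were 171 and 505 for H3K4me3, 903 and 1173 for H3K9cr, 3187 and 5612 for H3K27ac, and 2495 and 6527 for H3K27me3. The difference in H3K9cr covered length was -0.852 Mb. H3K4me3 was lost at 154 genes and H3K27ac at 293, and the difference was 126 for H3K27ac-marked genes and -175 for bivalent genes. From bivalent to H3K4me3 alone passed 299 genes and from H3K27me3 alone to bivalent 123, and 41.2% of bivalent genes with H3K27ac and 7.69% of those without lost H3K27me3. H3K9cr peaks touched H3K4me3, H3K27ac and H3K27me3 in 54.3%, 92.8% and 17.5% of cases in control and 55.4%, 89.5% and 14.8% after crotonate.

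With equal numbers of best-scored peaks, gains were 801 H3K4me3 and 9182 H3K27me3 peaks, in place of 1239 and 15704. This setting shortened only the crotonate list of each mark. Losses of peaks could therefore not become fewer, and the excess of gained over lost peaks could not become larger. The difference was -146 for H3K27ac-marked genes, which changed direction, and -712 for H3K27me3-marked genes, 303 genes gained H3K27me3, 33.0% of bivalent genes with H3K27ac lost H3K27me3, and 34 genes lost H3K27ac and H3K27me3 together. List counts were 1 H3K27ac gain for neuronal differentiation, 7 H3K4me3 gains for germ-layer regulators, 1 for pluripotency and 2 for Wnt and related signalling, 1 H3K27me3 loss each for cell cycle and choroid plexus genes, 1 H3K27me3 gain each for acyl-CoA and microglia genes, 2 H3K27ac losses for the stress list, 0 H3K27ac and 0 H3K27me3 gains for endothelial genes, and 0 H3K27ac gains for choroid plexus genes.

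With windows of 500 bp the difference for H3K27ac-marked genes was -48, a change of direction, and 35.3% of bivalent genes with H3K27ac lost H3K27me3. With windows of 2 kb the differences were 75 for H3K27ac-marked and -235 for H3K27me3-marked genes, and that share was 22.5%. List counts at 2 kb were 1 H3K9cr loss for neuronal differentiation, 0 H3K27ac losses for astrocytes, 11 H3K4me3 and 5 H3K9cr gains for Hox genes, 2 H3K27ac and 2 H3K27me3 gains for germ-layer regulators, 1 H3K4me3 gain for pluripotency, 1 H3K27ac gain for the stress list, 2 H3K27ac gains for choroid plexus and 1 H3K27me3 gain for acyl-CoA genes. Losses of H3K27me3 at 2 kb were 1 for the oligodendrocyte lineage, 3 for Wnt and related signalling, 0 for cell cycle arrest, 1 for cell cycle, 1 for acyl-CoA, 0 for Polycomb and 1 for endothelial genes.

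At H3K4me3-marked ends the differences were 141 for H3K9cr-marked genes, -78 for H3K27ac-marked genes, a change of direction, and -610 for H3K27me3-marked genes. Losses and gains there were 43 and 184 for H3K9cr and 280 and 202 for H3K27ac, and H3K27me3 was gained at 85 genes. With gene bodies the differences were 120 for H3K27ac-marked and -104 for H3K27me3-marked genes. With unshared peaks only, 30 genes lost H3K4me3 and the difference for H3K27ac-marked genes was 63. The lists then had 1 H3K9cr loss for neuronal differentiation, 0 H3K27ac losses for astrocytes and 0 for pluripotency, 1 H3K27me3 gain for acyl-CoA genes, and H3K27me3 losses of 2 for Wnt and related signalling, 0 for cell cycle arrest, 1 for acyl-CoA and 1 for Polycomb genes.

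When the peaks of a bivalent gene had to overlap each other, 26.1% of those with H3K27ac lost H3K27me3. On autosomes only, 1.46% of bivalent genes without H3K27ac lost it, and 53.1% of crotonate H3K9cr peaks touched H3K4me3. With at least 50% of the H3K9cr peak covered, H3K4me3, H3K27ac and H3K27me3 covered 48.2%, 85.3% and 13.1% of control peaks and 50.0%, 73.9% and 10.9% of crotonate peaks.

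Against random lists matched on state and peak strength, the percentile was 97.2 for H3K27me3 losses of neural stem and progenitor genes, 96.2 for H3K27ac losses of neuronal genes, 1.74 for Hox H3K4me3 gains, which had been above and were then below, 0.935 for Hox H3K9cr gains and 49.8 for Hox H3K27me3 losses. Germ-layer regulators stood at 87.8 and 46.7 for H3K4me3 and H3K9cr gains and at 91.6 and 36.9 for H3K27ac and H3K27me3 losses. Wnt and related signalling stood at 59.5 and 51.4 for the same gains and at 81.6 and 97.9 for the same losses, and the stress list at 81.9 for H3K27ac gains. Losses of H3K27me3 among genes that gained H3K4me3 stood at 15.6. With such lists and unshared peaks only, the percentile was 87.5 for H3K27ac losses of neuronal genes, 4.47, 0.935 and 50 for Hox H3K4me3 gains, H3K9cr gains and H3K27me3 losses, 93.5, 48.2, 95.6 and 46.6 for germ-layer H3K4me3 gains, H3K9cr gains, H3K27ac losses and H3K27me3 losses, 44.4, 51.955 and 85.7 for the first 3 of these in Wnt and related signalling, 81.9 for H3K27ac gains of the stress list, and 99.7 and 98.6 for H3K27me3 losses and gains of housekeeping genes. The housekeeping losses include Rpl8 and Rpl32 and the gains are Rpl7 and Rps6, ribosomal protein genes whose peaks are uncertain.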

Other observations

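The test with H3K9cr was written before its result was seen; the other comparisons of this part were chosen after the data were seen. Gained H3K27me3 peaks lay close to control H3K27me3: 28.1% (27.4 to 28.8) lay within 1 kb of a control peak, 57.7% (56.9 to 58.5) within 5 kb and 78.1% (77.4 to 78.7) within 20 kb, against 4.03%, 8.11% and 18.8% for randomly placed peaks. The genes holding most of them were long ones, chosen after their values were seen: Slit3, an axon guidance ligand gene, with 51 gained and 19 lost peaks, Skap1 with 43 and 9, Tenm4 with 39 and 13, and Kcnq1, a potassium channel gene within an imprinted cluster, with 26 and 4. Lost H3K27me3 peaks were narrow. Of control peaks under 400 bp, 83.7% (79.7 to 87.2) of those touching H3K4me3 and 51.9% (50.7 to 53.1) of the others were lost, and of those of at least 2 kb 1.15% (0.780 to 1.64) and 0.215% (0.0866 to 0.443).

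Gained H3K27ac peaks inside genes lay mostly in genes with H3K27ac at an end, 87.7% (87.2 to 88.3), against 84.3% of lost and 82.3% of shared gene-body peaks, and such genes made up 68.4% of gene length. Long genes again held most, chosen after their values were seen: Npas3, a transcription factor gene, with 45 gained and 43 lost peaks, Csmd2 with 38 and 2, Xylt1 with 38 and 16, Nav2 with 36 and 13, Ksr1, a scaffold of the Ras pathway, with 31 and 7, and Dock1 with 30 and 3. In the 7095 genes over 20 kb with H3K4me3 at 1 end, 32.7% (31.8 to 33.6) of gained H3K27ac summits lay in the part farthest from that end, of 4 equal parts of the gene, against 23.6% (22.6 to 24.7) of lost and 22.5% (21.9 to 23.2) of shared ones.

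The hypothesis that acylation in general reached further into marked genes was tested with H3K9cr, gained against lost summits, and was not borne out. Of gained H3K9cr summits inside genes 20.8% (19.1 to 22.6) lay in that far part, against 25.2% (23.2 to 27.2) of lost ones. Among shared ones the share was 19.1% (18.2 to 20.0), so the outcome rests on the lost ones. The gain of H3K27ac in the far part of genes was found and examined on the same 2 lists, and its cause stays open.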
